A study of Solanum lycopersicum with 8 samples.

How the data were processed

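RNA was measured by sequencing in young leaves of tomato seedlings of 2 genotypes, the cultivar M82 and the procera mutant proΔGRAS. All seedlings had been treated with paclobutrazol, an inhibitor of gibberellin (GA) synthesis, at 10 mg/l daily for 3 days. One set of each genotype then received 100 µM GA3 and was sampled 3 hours later. The 4 groups held 2 libraries each. Per the labels' protocols, libraries were made with the TruSeq RNA Sample Preparation Kit v2, a kit that does not mark strand, and all 8 were multiplexed on 1 lane.

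The deposited table holds raw read counts per gene for 34722 gene identifiers and, per the file headers, a second block of 8 columns of DESeq-normalized counts. The submitters' processing notes list TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3. The genome build, annotation version and counting options were not given in the sources used here. Only the raw counts, as deposited by the authors, were analysed, and the 8 normalized columns were not used. No row lacked a gene identifier. The table calls the mutant "null". The titles number the libraries of each group 1 and 2, whereas 3 columns carry the number 3. These 3 columns show their group but not their sample, and 5 columns matched a title in genotype, treatment and number. Libraries are named below by the number in the table. The series' design text states biological replicates but not whether they were separate plants or pools, so p-values measure the spread between these libraries. No 2 libraries of a group were copies of one another: chi-square per degree of freedom between them ranged from 36.4 to 89.1.

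The identifiers are not paired with gene names in the table, and 0 of 34722 matched the tomato gene table used here (41476 genes). Genes are therefore given by identifier, with at most 2 higher and 2 lower per comparison. The 38 gene lists fixed by description, the level of the PROCERA transcript and any coordinates were not analysed here for the same reason. The chromosome number is the one the identifier carries.

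Total counts ran from 14395465 to 18483028 per library. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), which left 18340 genes holding 99.94% of the counts. Counts were scaled with TMM factors and tested with edgeR 4.0.16's quasi-likelihood test (robust fit) in R 4.3.3, in one model of the 4 groups without a block, with 4 residual degrees of freedom. The 5 contrasts were the GA effect in each genotype, the genotype effect without and with GA, and the difference of the GA effects. Adjusted p-values are Benjamini-Hochberg over the genes tested, and "called" means an adjusted p under 0.05. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Levels are CPM, edgeR's read counts scaled to library size and TMM factor, as mean ± SD of 2 libraries unless stated. For a gene with a count of 0 in a whole group, the fold is a lower bound from a floor of 3 counts over that group. Where a gene had no count in any library of a genotype, the floor was spread over the 4 libraries of that genotype. Its fold then compares the genotypes with both treatments pooled. Such bounds cover counting error only. The rule for named genes took the highest and lowest log2 fold changes among called genes with a mean of at least 1 CPM whose groups did not overlap. Its criterion of a described function could not be applied. Where no gene was called in a direction, the gene with the smallest p is given and was chosen after its values were seen.

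The procedure was tested on simulated counts for all 18340 genes with the real means, dispersions and library sizes and 200 changed genes, 100 at each fold. For the GA effect in M82, edgeR recovered 7% of 2-fold and 60% of 4-fold changes and called 10 unchanged genes. DESeq2 1.42.0 recovered 13% and 65% and called 26 unchanged genes. For the GA effect in the mutant, edgeR recovered 3% and 66% and DESeq2 20% and 77%. For the genotype effect without GA, edgeR recovered 4% and 50%, and for that with GA 3% and 57%. For the difference of the GA effects, edgeR recovered 0% and 16%.

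Alternatives fixed before the data were examined were another scaling (RLE, or library totals only), no filter or a stricter one (5 CPM in 2 libraries), DESeq2 with no independent filtering, a fit of the 4 compared libraries alone, the replicate number as a block, a fold threshold, and leaving out each library. The library then left alone in its group is assumed to vary like those of the other groups. Lists of genes at unadjusted p under 0.01 in the M82 comparison were tested as sets with limma 3.58.1 (camera with a correlation of 0.01 or an estimated one, and fry) on log2 CPM with a prior count of 2. These set tests, the held-out lists and a block of number 1 against the other library were chosen after seeing the data. For comparisons that share the M82 control libraries, 20 data sets with no change in any group were simulated.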

Results

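Gene expression was measured in young leaves of paclobutrazol-treated tomato seedlings, with or without a GA3 application, in M82 and in proΔGRAS. M82 is a cultivar with a functional PROCERA gene, which encodes the tomato DELLA protein, a repressor of GA responses. The proΔGRAS line (the mutant) is a procera mutant. The comparisons ask which transcripts respond to GA within 3 hours, which of these responses remain when DELLA is lost, and how the mutant differs from M82. Each of the 4 groups held 2 libraries. The M82 libraries held 14696338 and 14395465 counts without GA and 17757386 and 17585593 with GA. The mutant libraries held 18483028 and 17782393 without GA and 18153672 and 17063766 with GA.

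The genotypes separated along the first principal component, which held 36.5% of the variance. The M82 libraries lay between -67.4 and -8.35 on it and the mutant libraries between 23.4 and 58.1. The second component (17.6%) separated the M82 libraries by number. Those with number 1 lay at 65.9 without and 23.3 with GA, and the others at -15.2 and -30.1. The M82 GA libraries, at 36.3 and 39.4, lay above all others on the third component (16.4%). On it, the mutant GA libraries, at -6.30 and 3.74, lay between the mutant libraries without GA, at -22.9 and 8.79. M82 library 3 without GA and M82 library 2 with GA stood apart at the low end of the first component. In these 2 libraries the 100 most abundant genes took 45.5% and 50.3% of the counts, against 31.4% to 41.3% in the other 6, and correlations of log2 CPM across genes between the 2 libraries of a group were lowest in M82 without GA (0.945).

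**Figure D1:**
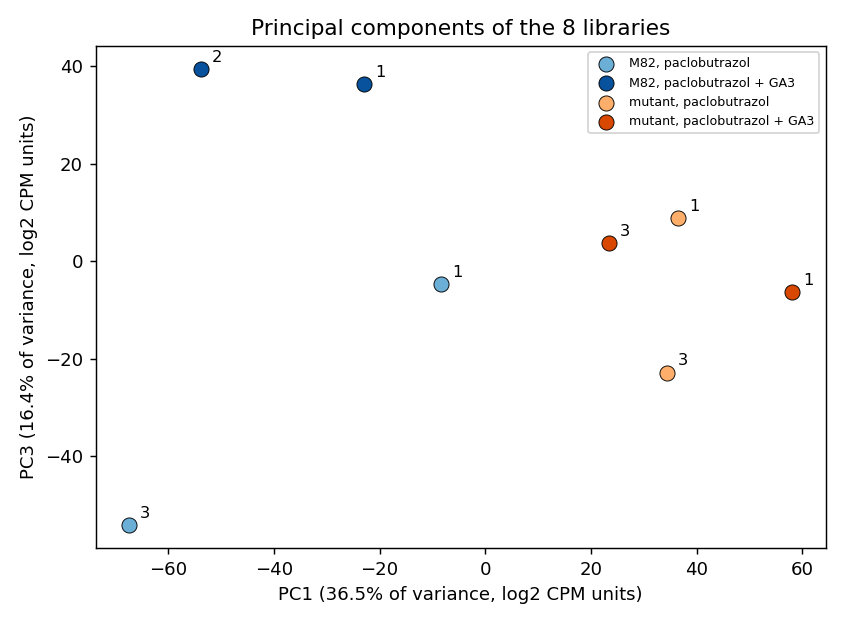
Principal components of log2 CPM over 18340 genes, with component 1 (36.5% of variance) on the x axis and component 3 (16.4%) on the y axis. Component 2 (17.6%) is not shown. Each point is 1 library, coloured by group and marked with its number in the table; the mutant libraries lie right of the M82 libraries, and the M82 libraries with GA3 lie at the top.

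In M82, GA raised 3 genes and lowered none at an adjusted p under 0.05 (edgeR quasi-likelihood test), with 1398 genes at an unadjusted p under 0.05 where 917 are expected by chance. Solyc04g081790.2, on chromosome 4, rose from 3.15 ± 0.573 to 17.3 ± 1.90 CPM (SD, n = 2), a log2 fold change of 2.47 (SE 0.285, edgeR adjusted p = 0.0471). Solyc07g062710.2, on chromosome 7, rose from 3.71 ± 1.03 to 20.5 ± 0.630 CPM, a log2 fold change of 2.45 (SE 0.283, edgeR adjusted p = 0.0471). Among genes with lower levels after GA, Solyc12g099900.1 had the smallest p, with 17.7 ± 4.68 CPM without and 4.02 ± 0.763 CPM with GA (edgeR adjusted p = 0.0557). Higher levels outnumbered lower ones among the strongest differences: of the 359 genes at an unadjusted p under 0.01, where chance gives 183, 276 were higher and 83 lower after GA, with median log2 fold changes of 1.30 and -1.31. DESeq2 called 92 genes up and 16 down, among them the 3 called by edgeR. Simulated data of this size held 100 changed genes at each fold. In them DESeq2 called 26 unchanged genes beside 13% of the 2-fold and 65% of the 4-fold changes. There edgeR called 10 unchanged genes beside 7% and 60%. These numbers do not give the share of false calls in the real data, where the number of true changes is not known. The edgeR count was 14 without M82 library 1 without GA, with 7 genes up and 7 down and 1 of them among the 3, and 0 without any 1 of the other 7 libraries. It was also 0 with library totals as the only scaling, with the stricter filter and in a fit of the 4 M82 libraries alone, and it was 92 without the filter. Solyc12g099900.1 was called without M82 library 1 without GA (adjusted p = 0.0314), and Solyc04g081790.2 was not called there (adjusted p = 0.0563).

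In the mutant, GA changed no gene at an adjusted p under 0.05, and 489 genes had an unadjusted p under 0.05, fewer than the 917 expected by chance. The 4 groups shared an estimate of the spread, though their libraries differed unequally. Chi-square per degree of freedom was 36.4 in the mutant and 89.1 in M82 without GA, and 57.4 and 55.3 with GA. Fits of each genotype alone called 0 genes in M82 and 3 in the mutant. Counts of calls and of unadjusted p-values therefore do not rank the GA responses of the genotypes. DESeq2 called 27 genes up and 2 down. Simulated data for this comparison held 100 changed genes at each fold. In them DESeq2 called 24 unchanged genes beside 20% of the 2-fold and 77% of the 4-fold changes. There edgeR called 9 unchanged genes beside 3% and 66%. How many genes truly change with GA is not known, so these numbers do not give the share of false calls in the real data. The smallest edgeR p belonged to Solyc09g008670.2, on chromosome 9, which had 2.62 ± 0.540 CPM without GA and 31.7 ± 10.8 CPM with GA (SD, n = 2; log2 fold change 3.59, SE 0.418; edgeR adjusted p = 0.15, DESeq2 adjusted p = 7.79e-13). In M82 the same gene had 7.19 ± 3.88 CPM without and 23.4 ± 2.06 CPM with GA (log2 fold change 1.71, edgeR adjusted p = 0.258, DESeq2 adjusted p = 0.0122). Among lower levels, Solyc02g067790.2 had the smallest p, at 6.36 ± 1.40 CPM without and 1.31 ± 0.249 CPM with GA (edgeR adjusted p = 0.758, DESeq2 adjusted p = 0.00893). The edgeR count was 2 without either M82 library without GA, 4 without mutant GA library 3, 3 in a fit of the 4 mutant libraries alone and 9 without the filter. Solyc09g008670.2 was called without M82 library 1 or 3 without GA (adjusted p = 0.00552 and 0.00488) and without mutant library 3 with GA (adjusted p = 0.0499).

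No gene was called for GA in both genotypes by edgeR. DESeq2 called 4 genes up and 1 down in both, against 0.135 and 0.00174 expected of independent lists; the GA effects of the genotypes share no library. Across 18340 genes, which are not independent replicates, the log2 fold changes of the GA effects correlated with Pearson r = 0.112 and Spearman rho = 0.0935. The 276 genes higher after GA in M82 at an unadjusted p under 0.01 had a median log2 fold change of 0.138 in the mutant (quartiles -0.0649 and 0.433), against 1.30 in M82. Of these, 181 (65.6%) were higher after GA in the mutant, and 8 were called there when adjusted over the list alone. For this list, which was not fixed in advance, the set test gave p = 1.43e-07 with the preset correlation (camera), p = 0.00693 with an estimated correlation and p = 0.00953 with fry, or 2.86e-07, 0.0139 and 0.0191 adjusted over the 2 lists. The estimated correlation was 0.0108, near the preset 0.01, so the correlation does not account for the gap between the camera p-values. With 2 libraries per group, the far smaller camera p is not read as a measure of the spread between libraries. The 83 genes lower in M82 had a median of -0.159 in the mutant, and 51 (61.4%) were lower, with p = 0.0361 with the preset correlation, p = 0.285 with an estimated correlation and p = 0.323 with fry, each equal to its adjusted value. The medians in M82 were the same with the 1 and 2 genes at 0 in a whole group set to their bounds. Relative to the median of all genes, the medians in the mutant were 0.147 to 0.148 and -0.150 to -0.142 over the 3 scalings. Leaving out single mutant libraries gave medians of 0.101 to 0.170 for the first list. For the second list the median was -0.174 on log2 CPM with all libraries, -0.0359 without mutant library 3 without GA and -0.0368 without mutant library 3 with GA.

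**Figure D2:**
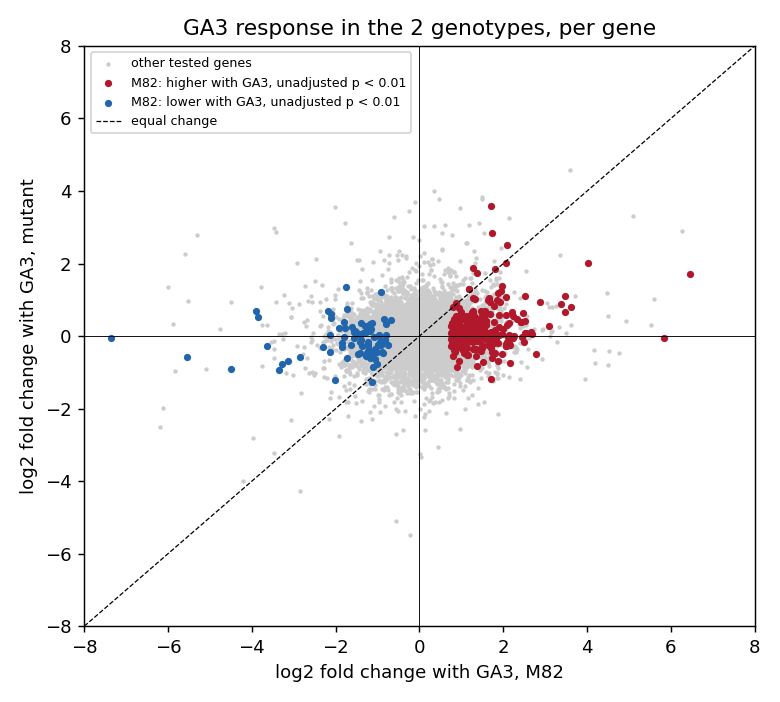
Log2 fold change with GA3 in M82 (x axis) and in the mutant (y axis) for each of 18340 tested genes. Coloured points are the 276 genes higher and 83 lower after GA in M82 at an unadjusted p under 0.01, whose medians in the mutant were 0.138 and -0.159; the dashed line marks equal change.

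Because genes chosen on their M82 change overstate it, 200 genes with a mean of at least 5 CPM were chosen in 1 pair of M82 libraries, with and without GA, and measured in the others. Genes highest after GA in the pair of number 1 (median 1.43) had a median log2 change of 1.03 in the other M82 pair and of 0.174 in the mutant. Genes highest in the other pair (median 1.68) had medians of 0.809 in the number 1 pair and 0.0465 in the mutant. Genes lowest after GA in the 2 pairs had medians of -0.758 and -0.715 in the held-out M82 pair and of -0.159 and -0.188 in the mutant. Among 10000 random lists matched on mean expression, the mutant medians of the genes chosen as highest lay at the 100th and 99.4th percentile, and those of the genes chosen as lowest at percentile 0. These percentiles describe these libraries only.

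The difference of the GA effects, tested as an interaction, called no gene with edgeR, with 689 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.546. DESeq2 called 20 genes, 6 with a higher and 14 with a lower GA effect in the mutant. The smallest edgeR p belonged to Solyc07g062710.2, which had 12.8 ± 1.5 CPM in the mutant without GA and 12.4 ± 2.24 CPM with GA, a difference of GA effects of -2.49 (SE 0.382, edgeR adjusted p = 0.546, DESeq2 adjusted p = 0.00193). Solyc03g119530.2 had 5.17 ± 0.568 CPM without and 1.13 ± 0.204 CPM with GA in M82, and 3.90 ± 0.128 CPM without and 6.27 ± 0.689 CPM with GA in the mutant (difference 2.86, SE 0.457; edgeR adjusted p = 0.546, DESeq2 adjusted p = 0.00565). In simulated data edgeR recovered 0% of 2-fold and 16% of 4-fold differences of this kind and DESeq2 3% and 45%, with 22 unchanged genes called by DESeq2. The edgeR count was 14 without the filter and 1 without M82 library 1 without GA.

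Without GA, 72 genes differed between the genotypes, 54 higher and 18 lower in the mutant, with 1871 genes at an unadjusted p under 0.05 (edgeR quasi-likelihood test). Solyc11g008420.1, on chromosome 11, had no count in any M82 library and 13.4 ± 2.23 CPM over the mutant libraries (SD, n = 4). With both treatments pooled this is at least 269-fold higher, and the edgeR adjusted p without GA was 0.00539. Solyc01g081250.2, on chromosome 1, was likewise at 0 in all M82 libraries and at 4.59 ± 1.37 CPM in the mutant (SD, n = 4). Pooled in the same way it was at least 91.8-fold higher, and its edgeR adjusted p without GA was 0.0295. Solyc03g006880.2, on chromosome 3, fell from 73.8 ± 7.72 CPM in M82 to 1.54 ± 1.38 CPM in the mutant (log2 fold change -5.59, SE 0.689, edgeR adjusted p = 0.0236). Its M82 level with GA was 7.26 ± 2.53 CPM (log2 fold change -3.35, edgeR adjusted p = 0.147, DESeq2 adjusted p = 1.81e-06). Solyc01g109500.2 fell from 183 ± 45.7 to 5.39 ± 3.15 CPM (log2 fold change -5.09, SE 0.712, edgeR adjusted p = 0.0323). Its M82 level with GA was 74.4 ± 13.2 CPM, a GA effect called by neither tool (log2 fold change -1.30, edgeR adjusted p = 0.665, DESeq2 adjusted p = 0.45). Without mutant library 1 or 3 without GA, adjusted p-values were 0.192 and 0.120 for Solyc01g081250.2, 0.192 and 0.0868 for Solyc03g006880.2 and 0.235 and 0.138 for Solyc01g109500.2, and without M82 library 3 without GA they were 0.0548, 0.0632 and 0.122. That of Solyc11g008420.1 was 0.0735 without mutant library 3 without GA, and that of Solyc01g109500.2 was 0.0632 and 0.0692 without M82 libraries 1 and 2 with GA. DESeq2 called 296 genes up and 116 down, including all 72. The edgeR count was 172 (108 up, 64 down) and 18 (8 up, 10 down) without M82 libraries 1 and 3 without GA, 44 and 43 without M82 libraries 1 and 2 with GA, and 2 and 1 without mutant libraries 1 and 3 without GA. It was 338 without the filter.

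**Figure D3:**
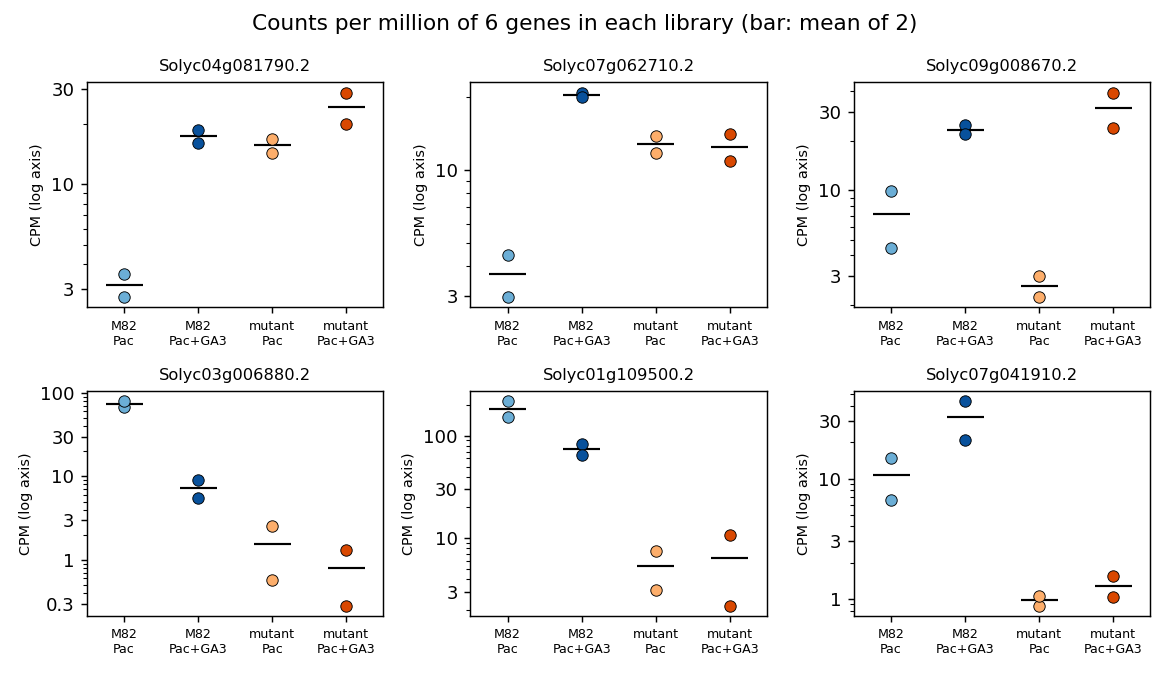
TMM-scaled CPM (log y axis) of 6 genes named in the text, by group on the x axis. Points are libraries and bars the mean of 2. The mutant without GA3 lies near the M82 libraries with GA3 for Solyc04g081790.2 (15.6 and 17.3 CPM). For Solyc07g062710.2 it lies between the M82 groups (12.8 CPM, against 3.71 without and 20.5 with GA3). It lies below both M82 groups for Solyc03g006880.2, Solyc01g109500.2, Solyc07g041910.2 and Solyc09g008670.2, the last at 2.62 CPM against 7.19 without and 23.4 with GA3.

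The 3 genes that rose with GA in M82 were all also higher in the mutant without GA, against 0.00883 expected of independent lists and at most 1 in 20 simulated data sets with no effects. Solyc04g081790.2 was at 15.6 ± 1.76 CPM in the mutant without GA (log2 fold change against M82 2.32, SE 0.284, edgeR adjusted p = 0.0234) and Solyc07g062710.2 at 12.8 ± 1.5 CPM (1.77, SE 0.280, edgeR adjusted p = 0.0357). With DESeq2 the shared calls were 40 up and 5 down, against 1.48 and 0.101 expected of independent lists. The comparisons share the 2 M82 libraries without GA. The values for independent lists leave out this sharing and the simulated ones leave out all effects. Without effects few genes are called, so few shared calls could arise there. An excess over either is therefore not a shared effect, and part of it may come from the shared libraries. The edgeR count was 12 (6 up, 6 down) without M82 library 1 without GA and 0 without any 1 of the other 7 libraries, and it was 36 without the filter and 0 where the count for GA in M82 was 0. The correlation of the fold changes was 0.396 over 18340 genes, below the mean of 0.516 in the simulated data sets. The covariance was 0.190 against 0.140 simulated, a difference of 0.0498. The simulation gave every group the same spread per gene. The shared M82 libraries without GA were the least alike of any group (correlation 0.945), so this difference may come from them. The 276 genes higher with GA in M82 had a median genotype difference of 0.766 and 85.9% were higher in the mutant, and the simulated lists gave 0.770 and 95.4%. Measured against the M82 library without GA that had not been used to choose them, the genes highest after GA had medians of 0.333 and 0.450 in the mutant without GA, and the genes lowest after GA had medians of 0.641 and -0.258. The latter differed in sign between the 2 choices.

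With GA, 65 genes differed between the genotypes, 35 higher and 30 lower in the mutant, with 2699 genes at an unadjusted p under 0.05. With library totals as the only scaling the split was 56 higher and 11 lower. Solyc11g008420.1 and Solyc01g081250.2 again had the highest fold changes (edgeR adjusted p = 0.00502 and 0.0290). Solyc12g062200.1, on chromosome 12, was at 5.70 ± 2.36 CPM in M82 (SD, n = 2) and had no count in the mutant, at least 75.9-fold lower (edgeR adjusted p = 0.0173). Solyc07g041910.2, on chromosome 7, was at 32.3 ± 16.3 CPM in M82 and 1.29 ± 0.353 CPM in the mutant (log2 fold change -4.64, SE 0.517, edgeR adjusted p = 0.0191). Its M82 level without GA was 10.8 ± 5.85 CPM, so M82 with GA lay further from the mutant (GA effect in M82 1.585, edgeR adjusted p = 0.41, DESeq2 adjusted p = 0.103). Without M82 library 2 with GA the adjusted p-values of these 4 genes were 0.0536, 0.121, 0.0698 and 0.0911. Without mutant library 1 with GA those of Solyc01g081250.2, Solyc12g062200.1 and Solyc07g041910.2 were 0.0942, 0.0534 and 0.0942, and Solyc01g081250.2 was at 0.154, 0.0748 and 0.0759 without M82 library 1 with GA and without mutant libraries 1 and 3 without GA. DESeq2 called 280 genes up and 272 down, including all 65. The edgeR count was 236 and 216 without M82 libraries 1 and 3 without GA, 10 (4 up, 6 down) and 0 without M82 libraries 1 and 2 with GA, 14 (6 up, 8 down) without either mutant library without GA, and 8 (8 up, 0 down) and 36 (24 up, 12 down) without mutant libraries 1 and 3 with GA. It was 438 without the filter, 37 with the stricter filter and 172 in a fit of the 4 libraries compared.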

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

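The difference of the GA effects between the genotypes met the threshold for 20 genes with DESeq2 (6 with a higher and 14 with a lower effect in the mutant) and for 0 with edgeR's quasi-likelihood test, whose smallest adjusted p was 0.546. In the simulated data for this difference DESeq2 called 22 unchanged genes beside 45% of the 4-fold changes, and edgeR called 1 unchanged gene.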

How the results depend on the processing

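The block of number 1 against the other library was chosen after seeing the data. Counts are given in the order GA in M82, GA in the mutant, genotype without GA, genotype with GA, difference of GA effects, GA in both genotypes, and GA genes of M82 also called for genotype (3, 0, 72, 65, 0, 0 and 3 with edgeR). DESeq2 gave 108, 29, 412, 552, 20, 5 and 45. Without the filter (23786 genes) edgeR gave 92, 9, 338, 438, 14, 2 and 36, and its median prior degrees of freedom were 32.4 against 5.62. With the stricter filter (12257 genes, 4.53 prior degrees of freedom) GA in M82 gave 0, genotype with GA 37 and the last overlap 0. With library totals only, GA in M82 and the last overlap gave 0, and the median log2 fold change of all genes moved to 0.135 for GA in the mutant, 0.317 for genotype with GA and 0.198 for the difference. The fits of 4 libraries gave 0 for GA in M82, 3 for GA in the mutant, 172 for genotype with GA and 0 for the last overlap. In the replicate block on the table's numbers, M82 library 2 with GA was the only library with number 2. The fit thus in effect set that library aside, and its counts do not show what blocking alone does. This block gave 0 for GA in M82, 2 for genotype with GA and 0 for the last overlap. Under it Solyc04g081790.2 and Solyc07g062710.2 were not called for GA in M82 (adjusted p = 0.376 for both), nor Solyc11g008420.1, Solyc01g081250.2 and Solyc12g062200.1 for genotype with GA (0.0755, 0.154 and 0.144). The block of number 1 against the other library gave 33, 166 and 200 for GA in M82, genotype without GA and genotype with GA, and 17 for the last overlap. Deviations of same-numbered libraries correlated at 0.421 between the M82 groups and between -0.0218 and 0.18 for the other 5 pairs of groups, and the labels do not say that a number marks a shared origin. Leaving out 1 library gave 0 to 14, 0 to 4, 1 to 172, 0 to 236, 0 to 1, 0 to 0 and 0 to 12. The cause was not tested. RLE scaling and the fold threshold moved no count by over 1.5 times. No named gene reversed under the alternatives run for it; 127 of its values kept their side of the threshold, 44 lost the call and 9 gained it. The values that kept their side include those of genes not called in the main fit that stayed uncalled, whereas only called genes could lose a call. The alternatives for gene lists were not run, since the lists could not be formed. In simulated data with this depth, spread and number of libraries, most 2-fold changes were not recovered, and none of the 3 was varied.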

Other observations

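Of the tests given here, those of depth and of swapped labels on the M82 libraries were chosen after the result was seen. Some genes were detected in 1 genotype only, whatever the treatment. With at most 3 counts over the 4 libraries of one genotype and at least 1 CPM in every library of the other, 3 genes were found in the mutant only and 1 in M82 only, with a median level of 5.27 CPM where detected. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the one by genotype, and the highest count in any other split was 0. A share below 1 of 35 was not possible with these libraries, so the count went with genotype but chance is not excluded. Of these 4 genes, 2 were called between the genotypes without GA.

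Genes called between the genotypes lay side by side more often than randomly placed calls. Among consecutive tested identifiers, 3 pairs were called in the same direction without GA, where 10000 random draws gave a median of 0 and a 95th percentile of 1 (permutation p = 8e-04), and 3 pairs with GA (permutation p = 3e-04). The pair at Solyc07g041910.2 was called in both comparisons, with log2 fold changes of -4.64 and -4.29 with GA. A neighbour of Solyc04g081790.2 also lay in a called pair in both comparisons. The 2 permutation p-values thus rest partly on the same genes. Reads shared between similar or overlapping neighbours were not examined, as no gene sequences were used here. No chromosome held an excess or deficit of genotype calls after adjustment over chromosomes (smallest Fisher adjusted p = 0.0777, chromosome 2 without GA, 1 of 1927 tested genes).

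The M82 libraries separated by number as well as by treatment. In edgeR fits of these 4 libraries alone, 2367 genes had an unadjusted p under 0.05 between number 1 and the others, 1195 between treatments and 46 in the crossed split, with 0 genes called in each. The number 1 library had the higher total in both treatments, but by little. Totals were 14696338 against 14395465 without GA and 17757386 against 17585593 with GA, and they differed more between treatments. The median absolute log2 change was 0.304 between treatments and 0.357 between numbers. That gap is smaller than the 0.199 of the crossed split, so these medians alone do not decide on depth. The near-equal totals, with 2367 genes between numbers and 1195 between treatments, argue against total counts as the cause in these 4 libraries. The share of counts in the 100 most abundant genes also followed the numbers, at 36.9% and 41.3% in the number 1 libraries. It was 45.5% and 50.3% in the others, and stays open as a cause. A swap of treatment labels in 1 pair would turn the held-out change negative, whereas its lower value was 0.809. No biological explanation was tested, and a difference between plants, harvests or preparations stays open, since the labels name none.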
